A study of Homo sapiens with 2 samples.

How the data were processed

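The measurements are ChIP-seq peaks from ARP1 multiple myeloma cells that overexpressed DEAF1, with 1 library immunoprecipitated with an antibody against the DYKDDDK (Flag) epitope and 1 input library. Groups were taken from the antibody label of each sample. Per the submitters' processing notes, cutadapt, Trimmomatic, FastQC, Bowtie2 and MACS2 were used with the hg38 genome. Their versions, settings and order, the control given to the peak caller, the annotation tool and its release are not given in the sources used here. The authors deposited 1 annotated list of peaks, which was the only measurement used. Per the file headers, it gives each peak's position, summit, fold enrichment, -log10 p and -log10 q, the location class, the nearest gene and transcript and the distance to its TSS. The fold enrichment in the deposited list is a linear ratio to the local background of the caller, not a change between conditions. The -log10 p and -log10 q values were also deposited by the authors as their caller gave them, and the lowest -log10 q, 1.30, corresponds to a q-value of 0.0496. All scores were used only to describe, rank or filter peaks within this list. Positions are 1-based.

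The list holds no read counts, so the depth of the libraries is unknown. In MACS2 output the fold is (pileup + 1)/(background + 1) and p is a Poisson tail probability, so both values of a peak were solved together for a whole-number pileup. A whole number was found for 100% of the 15428 peaks within a relative error of 1e-05 (largest 6.9e-06), with no peak allowing more than 1 solution. The background then follows from the fold. Its lowest value, 1.80, was shared by 1245 peaks (8.07%). Pileups and backgrounds are thus computed from the deposited values. The 95% intervals of fold enrichment are exact Poisson intervals of the pileup with the background held fixed. They cover counting error only, and since a summit is a local maximum they do not cover the choice of its position. A weak peak with few fragments therefore has a wide interval, and a missing peak means only that none passed the caller's limit at this depth.

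Genes were taken from the deposited list as assigned by the authors, 1 per peak. Symbols were matched, directly or by an unambiguous older symbol on the same chromosome within 100 kb, to a gene table of the GRCh38.p14 assembly, which matched 14053 peaks (91.1%). That table gives no strand and no sequence. For the named promoter peaks of ERCC4, IL6ST, CYLD, CD8A, FN1 and SNAP25, as for those whose neighbour is named with the result, the summit lay inside another gene of that table and not inside the named one. A gene was counted as having a promoter peak when an assigned peak lay within 1 kb of a TSS by the deposited distance. The 17 gene lists, with 552 entries and 548 distinct genes measured, were fixed before the data were examined. So were the comparisons, their main settings and the rule for named genes, with departures given below. The count of each list was set beside 10000 random lists of the same size drawn from 19974 protein-coding genes on chromosomes 1 to 22 and X and matched on gene length in 10 bins. The median fold enrichment of a list was set beside random lists of genes with a promoter peak. Genes and peaks of 1 library are not replicates, so these percentiles are descriptions and no p-value between samples was computed. Peak positions were compared with 1000 random placements of the same widths on the same chromosomes within the span of annotated genes. The plan was to compare distances to a TSS and to leave out assembly gaps. Distances to either gene end were compared instead, and random placements could fall in gaps. Shares carry Wilson 95% intervals and densities exact Poisson 95% intervals. The limits for median fold enrichment of promoter and distal peaks are order-statistic 95% intervals over peaks.

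Named genes are RAD50 and the genes earlier studied as DEAF1 targets, the 10 strongest promoter peaks of protein-coding genes, the 5 strongest peaks over 10 kb from a TSS, and up to 3 members of each list with the strongest promoter peak, all by fold enrichment. Some genes that this rule takes are not reported here. NBN, MRE11, list members named for having no peak, and the gene families of the closing part were chosen after their values were seen. Windows of raised background were 1 Mb windows with at least 5 peaks whose median background was at least 2 times the median of all peaks.

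Alternatives were a -log10 q of at least 5, a fold enrichment of at least 5, the 25% of peaks with the highest -log10 q, removal of the 1% of peaks with the highest pileup, a promoter window of 3 kb, peaks at any distance, and random lists without matching. Distances to either end of genes in the reference table and removal of windows of raised background were added after the data were seen. The planned search for the TTCG core that DEAF1 binds, the removal of repeat-rich peaks, the matching of promoters on CpG content and the recomputation of distances to every TSS need sequence or transcript models not used here and were not run. Routines were tested on simulated data. All of 1943 simulated peaks gave the exact pileup (100%), 2% of 200 lists drawn at random lay above the random range, 97% of 200 lists with a share raised by 0.3 did, and 10 of 10 raised windows were found with 0 of 190 others. The simulated peaks spanned narrower ranges than the data, whose pileups were 8 to 6652 and backgrounds 1.80 to 51.9. Simulated genes were given peaks without regard to length, so the effect of length matching was not tested. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.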

Results

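Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out in ARP1 cells, an established human multiple myeloma line, that overexpressed DEAF1, a transcription factor that binds DNA through its SAND domain. Cells were cross-linked for 10 min in 1% formaldehyde. The data comprised 1 immunoprecipitated library, made with an antibody against the DYKDDDK (Flag) epitope, and 1 input library without antibody. The sample titles also name RAD50, a DNA repair gene, and the labels do not say which protein carries the epitope, so libraries were grouped by the antibody label. There were no replicates, and no library from cells without the overexpression was analysed here. Each value below therefore describes enrichment in 1 library over the local background of the peak caller, with no measure of spread between cultures. The total depth of the libraries is unknown. Pileups and backgrounds at the peak summits were recovered from the authors' fold enrichment and -log10 p of each peak. The median peak had 42 fragments at its summit (quartiles 23 to 84) over a background of 3.53. The intervals of fold enrichment, shares and densities cover counting error only.

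The first question was where in the genome the protein was recovered. The strongest peak lay over the start of FAF2, which encodes a factor of endoplasmic reticulum-associated protein degradation. It was enriched 1710-fold (95% Poisson interval 1669 to 1751) and had 6652 fragments at its summit, on chromosome 5 at 176446162 to 176449541 (hg38). The next strongest promoter peaks were those of SMARCE1, a subunit of the SWI/SNF chromatin remodeller, at 894-fold, the arginyltransferase gene ATE1 at 864-fold and UBE2M, which encodes a NEDD8-conjugating enzyme, at 823-fold. INO80, the ATPase of another chromatin remodeller, followed at 809-fold. The remaining members of the 10 strongest were CRAMP1 at 704-fold, RABEP2 at 515-fold, the riboflavin kinase gene RFK at 470-fold, CDK5R1 at 459-fold and the SMAD co-repressor gene SKI at 454-fold. For CRAMP1, the summit at 1610816 on chromosome 16 lay inside IFT140 in the reference gene table, and for RFK the summit lay inside GCNT1.

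**Figure D1:**
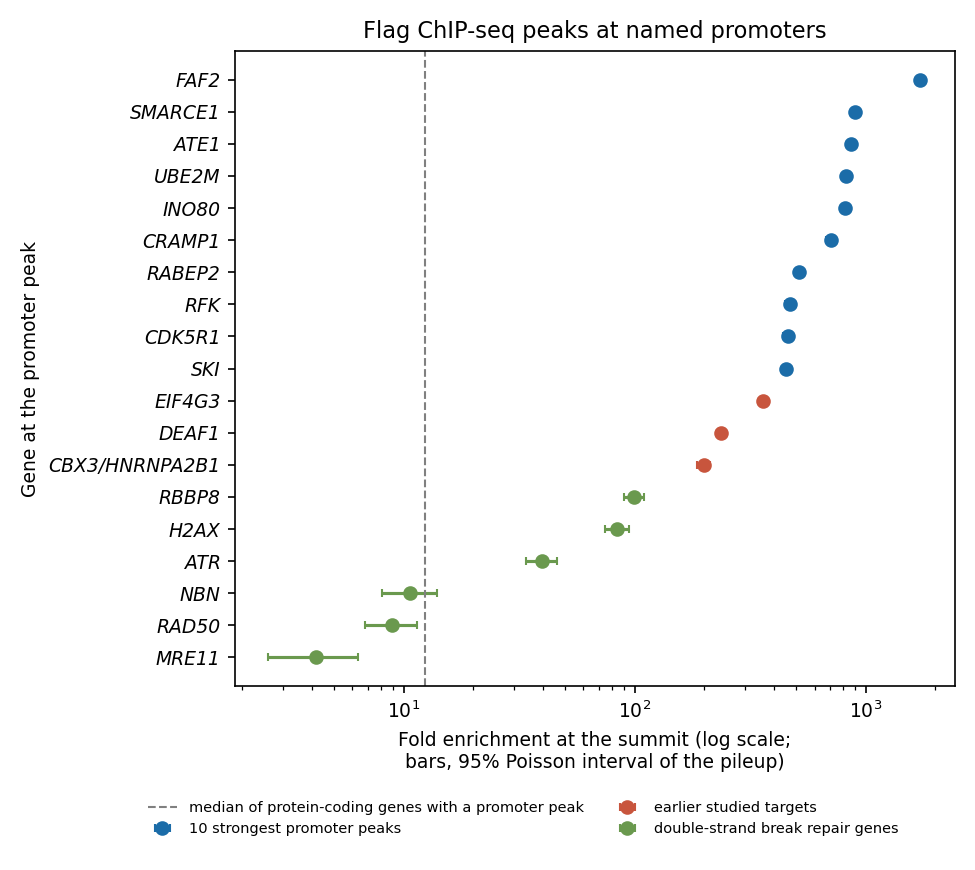
Fold enrichment over the caller's local background (horizontal log axis) at promoter peaks of the 10 strongest promoters, of earlier studied DEAF1 targets and of 6 double-strand break repair genes (vertical axis) in the 1 Flag immunoprecipitate; bars are 95% Poisson intervals of the summit pileup. FAF2 stands at 1710-fold, EIF4G3 at 360-fold and DEAF1 at 236-fold, while NBN (10.7-fold), RAD50 (8.88-fold) and MRE11 (4.16-fold) lie below the dashed line at 12.4-fold, the median of protein-coding genes with a promoter peak.

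The authors' list held 15428 peaks on 23 chromosomes, with a median fold enrichment of 8.92 (quartiles 5.0 to 17.8) and a highest q-value of 0.0496. Of these, 12119 peaks (78.6%, Wilson 95% interval 77.9 to 79.2%) lay within 1 kb of a transcription start site (TSS) by the authors' annotation, and 11049 (71.6%) were given a distance of 0. Distal intergenic sequence held 1221 peaks (7.91%) and introns 966 (6.26%). Exons held 107 peaks, 3' untranslated regions 99, downstream flanks 80 and 5' untranslated regions 11. A further 481 peaks were classed as promoter at 1 to 2 kb and 344 at 2 to 3 kb. Each peak has 1 class, and all those within 1 kb of a TSS were classed as promoter. The exon and 5' untranslated region counts therefore leave such peaks out. Measured instead against either end of a protein-coding gene in the reference gene table, which gives no strand, 63.6% of peaks lay within 1 kb, and random placement of the same widths on the same chromosomes gave a median of 4.33% and at most 4.90% in 1000 draws.

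Promoter peaks were stronger and wider than distal ones. Peaks within 1 kb of a TSS had a median fold enrichment of 10.9 (quartiles 6.29 to 20.3) and a median width of 991 bp, and the 1322 peaks over 10 kb from a TSS had 4.38 (3.57 to 6.17) and 411 bp. Median summit pileups were 52 and 20 fragments, over backgrounds of 3.67 and 3.47. The share of peaks within 1 kb of a TSS was 41.2% in the lowest of 10 equal groups by fold enrichment and 94.8% in the highest. Of the 275 peaks enriched at least 100-fold, 258 lay within 1 kb of a TSS and 7 over 10 kb away.

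**Figure D2:**
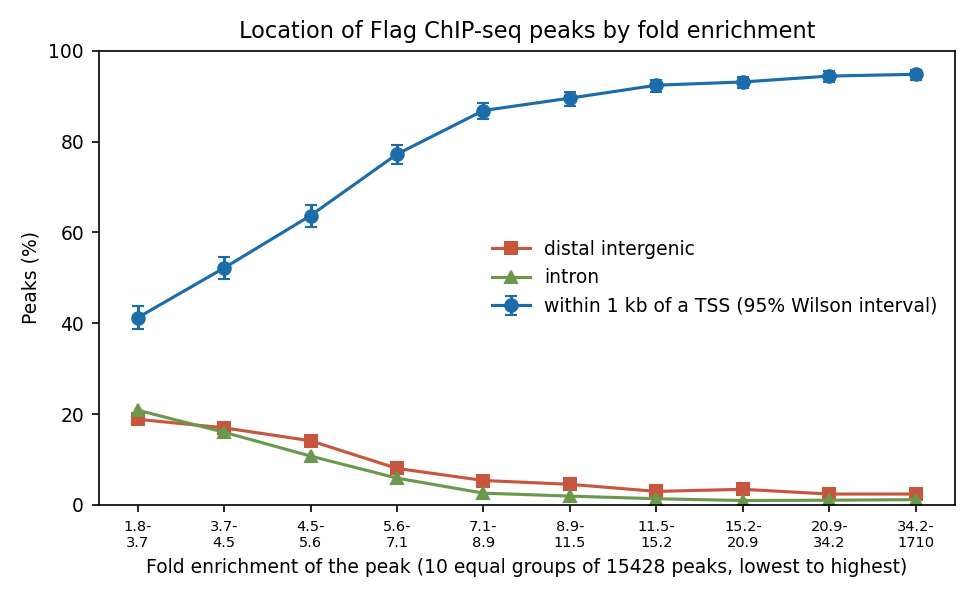
Share of peaks (vertical axis, %) within 1 kb of a TSS, in distal intergenic sequence and in introns, for 10 equal groups of the 15428 peaks ordered by fold enrichment (horizontal axis); bars are 95% Wilson intervals. The promoter share goes from 41.2% in the lowest group to 94.8% in the highest. Median width goes from 358 to 1659 bp, and wider peaks reach a TSS more easily.

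The strongest peak over 10 kb from a TSS was assigned to the insulin receptor gene INSR, on chromosome 19 at 7097621 to 7100489, 22669 bp from the start of the assigned transcript, which covers 7120620 to 7123158, with an enrichment of 337-fold (322 to 354). The next were assigned to MIR9-3HG on chromosome 15 at 250-fold, to RNU7-29P on chromosome 1 at 188-fold, to GNGT2 on chromosome 17 at 169-fold and to BSN-DT on chromosome 3 at 113-fold, and the authors annotated all 5 as distal intergenic. The summit of the INSR-assigned peak lay inside the uncharacterised gene LOC124904625 in the reference table.

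Because the titles name RAD50, its promoter was examined next. RAD50, the ATPase of the MRE11-RAD50-NBN complex that senses DNA breaks, had 1 promoter peak, on chromosome 5 at 132556768 to 132557285, over the annotated start at 132556930. It was enriched 8.88-fold (6.78 to 11.4), with 58 fragments over a background of 5.64 and a -log10 q of 35.3. By fold enrichment it ranked 7745 among the 15428 peaks, above 49.8% of them and above 34.7% of the 9961 protein-coding genes with a promoter peak. Its partners NBN and MRE11 had promoter peaks at 10.7-fold (8.06 to 13.9) and 4.16-fold (2.59 to 6.38). The RAD50 and NBN intervals overlap. RAD50 ranked 19 among the 37 double-strand break repair genes with a promoter peak.

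Of 5 genes earlier studied as DEAF1 targets, DEAF1 and EIF4G3 had assigned promoter peaks (random median 2, 0 to 4). With 5 genes no count could lie below that range and only 5 of 5 above it, so the comparison decides nothing. The DEAF1 promoter peak covered 693164 to 697742 on chromosome 11 and was enriched 236-fold (226 to 247), rank 74 of all peaks. Of 6 peaks within the DEAF1 gene (644233 to 707083 in the reference table), the other 5 had at most 18 fragments at the summit against 2013 here. EIF4G3, which encodes a scaffold of translation initiation, had a promoter peak on chromosome 1 at 21174742 to 21179008, enriched 360-fold (346 to 374), rank 22. HNRNPA2B1, an RNA-binding protein gene, had no assigned peak. A peak enriched 198-fold (186 to 211), which the authors assigned to CBX3, covers 26199328 to 26202540 on chromosome 7 and includes an end of HNRNPA2B1 at 26200746. The annotation gives each peak 1 gene, so a promoter that lies beside another can go without one. HTR1A and IFNB1 had no peak of any assignment in the gene or within 1 kb of it.

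DNA repair genes carried promoter peaks more often than length-matched random genes. So did most other lists, housekeeping genes (21 of 22) among them. Random lists were drawn from all protein-coding genes, of which 49.9% had a promoter peak, and were not matched on expression. Of 43 double-strand break repair genes, 37 had one, against a median of 26 in 10000 random lists (central 95%, 19 to 32). The strongest were at RBBP8, which encodes the end-resection factor CtIP (99.2-fold), at H2AX, the gene of the histone variant phosphorylated at breaks (83.8-fold, listed as H2AFX), and at the kinase gene ATR (39.6-fold). ATM, CHEK2, PRKDC, RAD51B, XRCC3 and XRCC6 had none assigned, which does not exclude a peak assigned to a neighbour. A peak assigned to any gene lay within 1 kb of an end of 40 of the 43 (random median 27). The median fold enrichment of the 37 peaks was 8.88, lower than in all but 1.35% of random lists of promoter-peak genes (random median 13.1). Of 40 Fanconi anaemia and other repair genes, 32 had a promoter peak (random median 22, 16 to 28), led by the nuclease gene ERCC4 at 194-fold, the mismatch repair gene MSH6 at 164-fold and FANCC at 45.4-fold. Among peaks enriched at least 5-fold, the double-strand break list held 28 genes, within the random range of 17 to 29, and among the 25% of peaks with the highest -log10 q it held 9 (range 4 to 15).

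**Figure D3:**
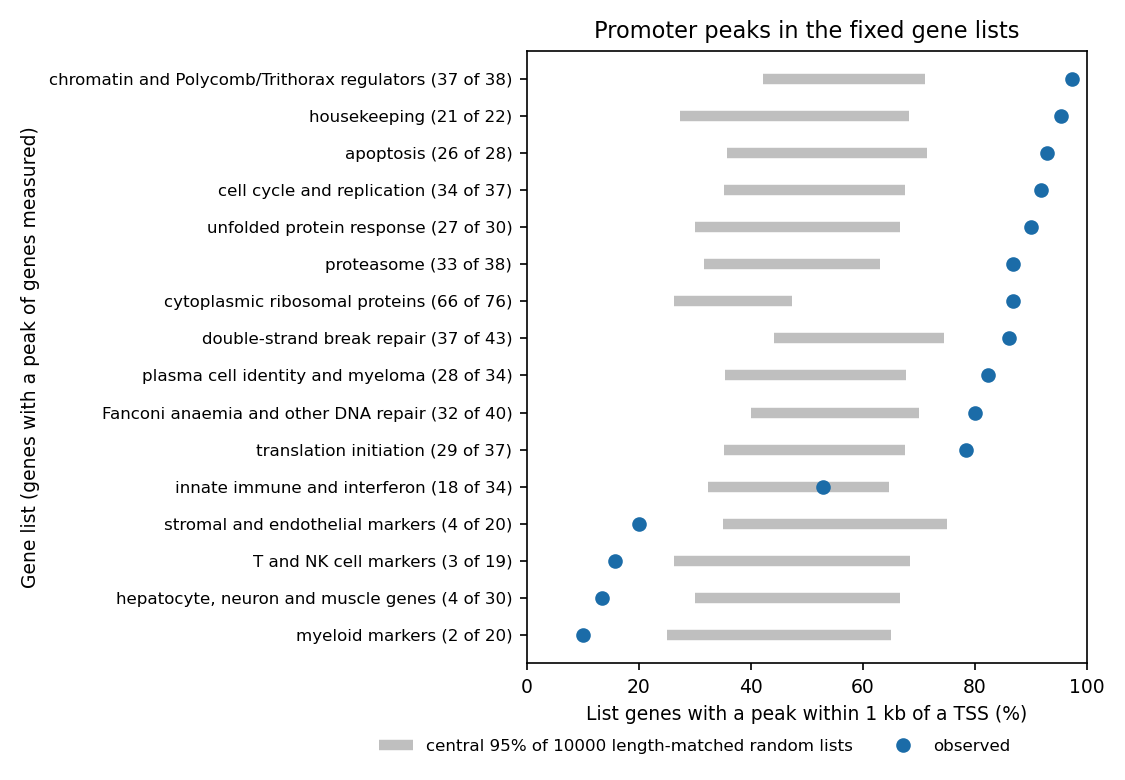
Share of genes with a peak within 1 kb of a TSS (horizontal axis, %) in the 16 fixed lists of more than 5 genes (vertical axis, with counts) in the 1 immunoprecipitate. Points are observed shares and grey bars the central 95% of 10000 random lists matched on gene length; 37 of 38 chromatin regulators and 2 of 20 myeloid markers mark the highest and lowest shares.

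Genes that define plasma cells or are altered in myeloma carried promoter peaks at 28 of 34 members (random median 17, 12 to 23). XBP1, a driver of plasma cell differentiation and of the unfolded protein response, was enriched 60.1-fold, the IL-6 co-receptor gene IL6ST 51.3-fold and the NF-kappaB regulator gene CYLD 34.1-fold. CD27, FCRL5, POU2AF1, SLAMF7 and TNFRSF13B were among those without an assigned promoter peak. The unfolded protein response list had 27 of 30 members with a peak (random median 15, 9 to 20), among them XBP1 and the disulfide isomerase genes PDIA3 at 52.2-fold and PDIA6 at 44.6-fold. PDIA6 lies in a stretch of chromosome 2 with raised background, 13.9 at this peak. In the proteasome list, 33 of 38 genes had a peak (random median 18, 12 to 24), with PSMD2 at 78.8-fold, PSMA7 at 40.6-fold and PSME4 at 27.0-fold, and the list's median of 7.57-fold was lower than in all but 0.490% of random lists. At least 5-fold enrichment left 22 proteasome genes, within the random range of 10 to 22.

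Cell cycle and replication genes had promoter peaks at 34 of 37 members (random median 19, 13 to 25), with the replicative helicase genes MCM3 at 78.0-fold, MCM7 at 27.6-fold and MCM4 at 26.8-fold, where the MCM7 summit lay inside AP4M1. Apoptosis genes had them at 26 of 28 (random median 15, 10 to 20), with the inhibitor of apoptosis gene BIRC2 at 178-fold and XIAP at 31.1-fold. FAS had none assigned. Innate immune and interferon genes were within the random range, with 18 of 34 (random median 17, 11 to 22). In that list IRF1 reached 47.9-fold and the DNA sensor gene CGAS 16.8-fold.

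Chromatin regulators had the highest share, 37 of 38 (random median 22, 16 to 27). The acetyltransferase gene CREBBP was enriched 355-fold, the methyltransferase gene KMT2D 101-fold and the DNA methyltransferase gene DNMT3B 84.0-fold. HDAC3 was the member without an assigned promoter peak. Cytoplasmic ribosomal protein genes had promoter peaks at 66 of 76 (random median 27, 20 to 36), led by RPL28 at 145-fold, RPL27A at 69.0-fold and RPL3 at 65.0-fold. Translation initiation genes had them at 29 of 37 (random median 19, 13 to 25), where EIF4G3 was followed by EIF2B4 at 116-fold and EIF4G2 at 55.4-fold. The summit of the EIF2B4 peak lay inside SNX17. Among 22 housekeeping genes, 21 had a peak (random median 10, 6 to 15), with NCL at 72.6-fold and YWHAZ at 38.9-fold, and POLR2A had none assigned, although a peak assigned to any gene lay within 1 kb of an end of all 22 (random median 12).

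Genes of lineages other than plasma cells carried fewer promoter peaks than length-matched random genes. No list was matched on promoter CpG content or on expression, so whether either accounts for the counts of any list was not tested. T and NK cell markers had 3 of 19 (random median 9, 5 to 13), at FOXP3 (9.63-fold), TBX21 (8.84-fold) and CD8A (3.54-fold). At FOXP3 the summit lay inside PPP1R3F in the reference table. Counting assigned peaks at any distance, 6 of the 19 markers had one, within the random range of 5 to 13. Myeloid markers had 2 of 20 (random median 9, 5 to 13), CEBPA at 15.7-fold and CD68 at 4.28-fold. Stromal and endothelial markers had 4 of 20 (random median 11, 7 to 15), including VIM at 11.6-fold, FN1 at 6.28-fold and COL1A1 at 6.14-fold. Of 30 hepatocyte, neuron and muscle genes, 4 had a peak (random median 15, 9 to 20), with MAP2 at 22.5-fold, SLC17A7 at 10.8-fold and SNAP25 at 6.42-fold. ALB, TTR, MYH7 and MYOD1 had none assigned. Of the 17 lists, 11 lay above the central 95% of random lists, 4 below and 2 within. The 2 within include the list of 5 earlier studied targets, which was too short to be placed. Among the 25% of peaks with the highest -log10 q, 4 lists lay above (unfolded protein response, apoptosis, ribosomal proteins and chromatin regulators) and 2 below.

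Peak density differed between chromosomes. Chromosome 19 had 19.7 peaks per Mb (95% Poisson interval 18.5 to 20.8) and chromosome 17 had 11.9, against 5.09 over all chromosomes. Chromosome 13 had the lowest density, 2.66 per Mb (2.37 to 2.97). Per 100 protein-coding genes, chromosomes 19 and 13 had 79.4 and 89.9 peaks, against 77.2 over all chromosomes, and the values ranged from 51.3 on X and 56.1 on chromosome 21 to 90.7 on chromosome 22. Peaks on X also had the lowest median background, 2.31 against 3.53 over all peaks. Whether lower coverage of X accounts for its few peaks was not tested.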

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

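The distances to gene ends and the removal of windows of raised background were chosen after the data were seen. Leaving out settings that cannot move a value, of 190 alternative values 144 stayed within their limit (a 95% interval, or 1.5 times for a count) and 46 moved. A count within its limit can still change its place against the random lists. The call changed for 2 of 17 lists at a fold of at least 5. Among the 25% of peaks highest in -log10 q it changed for 9 of 17. Of 128 counts for lists other than double-strand break repair, 21 moved. Stricter limits keep stronger peaks by construction, which by itself raises medians and lowers counts. With a -log10 q of at least 5, a fold of at least 5 and the 25% highest in -log10 q, in that order, the share within 1 kb of a TSS was 84.4, 88.3 and 94.5%, distal intergenic peaks were 6.12, 4.77 and 2.49%, intron peaks 4.02, 2.60 and 1.14%, the promoter median fold 11.8, 13.1 and 29.2, and the distal median 5.57, 7.49 and 27.8. The highest 25% had 3857 peaks, 9 double-strand break repair genes, 4 lists above the random range and 2 below. Among peaks with a -log10 q of at least 5, chromosome 13 had 2.25 and chromosome 19 had 16.9 peaks per Mb. A 3 kb promoter window gave 83.9% and a median fold of 10.3. Within 1 kb of either end of a protein-coding gene or of any gene lay 63.6% and 72.1%, and the cause of that difference from the annotated share was not tested. Counting peaks at either gene end, which 55.0% of protein-coding genes had, 17 of 17 lists had the same call, 8 counts were higher and 4 lower. Double-strand break repair then had 40 of 43 (random median 27). The filter for assembled chromosomes removed 0 peaks and tests nothing. The TTCG search, the repeat filter, CpG matching and recomputed TSS distances were not run. With 1 library, leaving out a replicate was not possible, and weak peaks rest on as few as 8 fragments.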

Other observations

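The gene families, the tRNA counts, the test of background at promoters, that of the DEAF1 construct and that of housekeeping genes were chosen only after the results were seen, and so were the limits used to read the ribosomal protein and copy gain tests. Families grouped by symbol split sharply. None of 392 olfactory receptor genes (random median 123) and none of 45 defensin genes (random median 14) had a promoter peak. Keratin and keratin-associated protein genes had 3 of 149 and protocadherin genes 7 of 65 (random medians 41 and 34). Mitochondrial ribosomal protein genes, with 58 of 77, lay above the central 95% of random lists (random median 33). So did E2 ubiquitin-conjugating enzymes with 31 of 36 (20) and Mediator subunits with 25 of 30 (15), random medians in parentheses. Spliceosomal SNRP and SF3 proteins with 17 of 21 (10) were above it too. Genes whose symbols start with NDUFA, NDUFB, NDUFC, NDUFS or NDUFV, not all of them NADH dehydrogenase subunits, were also above it with 36 of 46 (21). Zinc finger genes with ZNF symbols (266 of 517), solute carriers (197 of 386) and HOX genes (11 of 40) lay within it. HOX genes lay below the range of unmatched lists, whose median was 20 (0.245th percentile). Histone genes had 36 of 94, above the length-matched median of 22 but below the unmatched median of 47, so the direction of histone genes, and the call for HOX genes, depend on the matching.

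Transfer RNA genes, which RNA polymerase III transcribes, were overlapped by peaks at 169 of 443 (38.1%), against a median of 0.677% and at most 2.26% in random placements. For 87 of these genes the peaks lay over 1 kb from any annotated TSS. Of the 3309 peaks more than 1 kb from a TSS, 68 (2.06%) covered a tRNA gene, and their median fold enrichment was 6.42 against 4.48 for the other such peaks. Small nuclear RNA genes were overlapped at 36 of 154, with no random placement to set beside them. For 2 of these 36 the peaks lay only away from a TSS, unlike the 87 of 169 tRNA genes.

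The strongest peaks lay at promoters, which may reflect binding of the tagged protein or recovery of open, active promoters by any immunoprecipitate. A lower background at promoters is argued against, since the median pileup of promoter peaks was 2.60 times that of distal peaks while their backgrounds differed by 1.06 times. If transcription alone set peak strength, ribosomal protein genes would stand high, yet their median of 9.32-fold was at the 6.38th percentile of random lists. The 95% interval of that median, 8.11 to 12.4, reflects spread between genes. It includes the random median of 11.1, so this does not decide. Promoter peaks at 95.5% of housekeeping genes leave recovery of active promoters open, and no immunoprecipitate without the tagged protein was used here to tell both apart.

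The DEAF1 promoter held a peak of 2013 fragments in cells that overexpress DEAF1, which could come from an expression construct rather than from the chromosome. Construct reads in a control that also holds them would raise the background, which was 7.52 here, above that of 95.7% of all peaks but far below the pileup. Without them in the control, they would be called as peaks on other coding exons too, and the next highest peak in the gene had 18 fragments. These values argue against reads along a coding-sequence construct as the whole source, while binding to part of a construct, or a construct that carries the promoter, was not tested. Binding at the promoter of its own gene stays a hypothesis.

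Background was raised in runs, in 16 of 1153 windows of 1 Mb with 240 peaks, and the highest lay on chromosome 2 from 9 to 12 Mb at 12.6, or 3.56 times the median of all peaks. There it went from 1.80 at the ASAP2 peak at 9206295 to 19.8 at the ITGB1BP1 peak at 9422422, and other runs lay on chromosome 1 from 145 to 148 and 150 to 155 Mb and on chromosome 3 from 12 to 14 Mb. Single windows stood on chromosome 1 from 156 to 157 Mb and on chromosome 4, where they held 5 and 7 peaks. A random scatter of backgrounds over all peaks is argued against, since none of 1000 shuffles gave more than 4 such windows. The shuffles treat close peaks as independent, so they do not address backgrounds that neighbouring peaks share. Distal peaks inside the runs had 2.67 times the background of distal peaks elsewhere (9.25 against 3.47, 25 peaks). That argues against open chromatin at promoters alone, but only in part. These 25 peaks were among the 240 whose backgrounds chose the windows. DNA copy gain in the line may account for the runs, but it cannot be told apart here: the fold enrichment of promoter peaks inside was 0.770 times that elsewhere, because pileups were 1.63 times higher and backgrounds 2.30 times. Reads shared between near-identical copies of sequence on chromosome 1 were not tested.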
